A study of Mus musculus with 15 samples.

How the data were processed

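RNA from mouse liver was measured by sequencing of poly(A)-selected RNA in 15 libraries. The titles place 12 of them in 4 groups of 3, wild type on normal salt (WT NSD), wild type on high salt (WT HSD), labelled Sirt3 knockout on normal salt (KO NSD) and labelled Sirt3 knockout on high salt (KO HSD). The other 3 libraries carry a diet but no genotype in their titles; their characteristics name the wild type, and they are called the additional wild-type set (2 on high salt, 1 on normal salt). Per the labels, the high salt diet held 8% NaCl and the normal diet 0.4%, the mice were male C57BL/6 aged 6 months, and feeding began at 6 weeks of age. The labels disagree on how long the diet lasted, with 4 months in the protocol and the design text and 8 weeks in the characteristics.

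The authors deposited expected counts per gene for all 15 libraries in a single table, and the same expected counts with FPKM values (fragments scaled by effective length and by the library total) for each library. Per the submitters' processing notes the tools were Bowtie2 2.2.5 and RSEM 1.2.8 on genome build mm10. The gene annotation and the strandedness of the libraries are not given in the sources used here. RSEM shares reads that fit several genes between them, so values of near-identical genes (the Mup, Cyp2c, Cyp2d, Cyp3a and Cyp4a families, Sult2a, and zinc finger genes such as Zfp991, Zfp992 and Gm14326) are uncertain, as are those of overlapping and antisense genes. Gene-level counts cannot show an allele whose transcript lacks only some exons, and the Sirt3 allele is not given in the sources used here. The count table held 18131 genes identified by Entrez ID, of which 18009 matched a RefSeq row on GRCm38.p6, the assembly of mm10; coordinates come from there. Between 69.3% and 72.6% of the values per library were whole numbers. No sample column was left unmapped (0 columns).

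Expected counts were rounded to whole numbers. The 12 libraries of the 4 groups entered a single fit of 4 group means with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F test) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over the 13051 genes tested, with a threshold of 0.05. Adjusted p-values of single genes come from this test unless another tool is named. Contrasts were high against normal salt within each genotype, labelled knockout against wild type within each diet, and the difference between the salt effects (the interaction). The additional set was tested in a fit of all 15 libraries and 6 group means with 13864 genes; its lone normal salt library was assumed to vary like the other groups. Standard errors of log2 fold changes come from the same fits. Levels are given as CPM, counts scaled to the library total, with the SD between 3 libraries; group means come from the fit of 12 libraries, and values of single libraries and those in the plots from scaling over all 15. Every p-value measures only the spread between these samples, which may be technical, since nothing in the labels says that they came from separate animals. With 3 libraries against 3, an exact permutation test could not give a p below 0.1.

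The 37 gene lists hold 612 members found in the table. They cover inflammation (acute phase, inflammatory cytokines and NF-kB targets, NOD-like receptor and pyroptosis, interferon response, MHC class II presentation, complement and coagulation), cell types (Kupffer cell and macrophage, neutrophil, T and NK cell, B and plasma cell, stellate cell and matrix, sinusoidal endothelial, cholangiocyte, erythroid, and adipose, pancreas and muscle markers), metabolism (cholesterol synthesis, lipogenesis, fatty acid oxidation and PPAR-alpha targets, oxidative phosphorylation, bile acid metabolism and transport, gluconeogenesis and fasting, urea cycle and amino acid catabolism, xenobiotic P450 enzymes), SIRT3 (SIRT3 substrates, sirtuins, neighbours of Sirt3), and regulation (antioxidant and NRF2 targets, circadian clock and outputs, glucocorticoid and mineralocorticoid targets, osmotic response and renin-angiotensin system, male-biased and female-biased liver genes, unfolded protein response, heat shock, immediate early genes, proliferation, ribosomal proteins). Lists were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry, which asks whether a list's genes move in a common direction. No list call at the preset correlation held with an estimated correlation or in fry's directional test, in any of the 5 contrasts with all 12 libraries (0 lists). Per list, the number of genes past 0.05 adjusted over the list alone is given beside the number over all genes.

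The groups, contrasts, lists, tests and the rule for named genes were fixed before the data were examined, as were most alternatives. The rule took Sirt3 in every library, then per contrast up to 10 genes higher and 10 lower with the smallest p past the threshold, a group mean of at least 1 CPM and no overlap between the libraries compared (or the 3 with the smallest p, where none passed), up to 4 members of each list called by camera, and 3 members each of the acute phase, inflammatory, NOD-like receptor, Kupffer cell, antioxidant, SIRT3 substrate and fatty acid oxidation lists. Genes named outside it (the Y-linked and X-linked genes, Sult2a1, Arntl, Cfd, Cidea, Miox, Gm14288, Irf1 and genes of shared windows) were chosen after their values were seen.

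Alternatives were other scalings (DESeq2 size factors, upper quartile), DESeq2 1.42.0, limma-voom with sample weights, no filter and a stricter filter (1 CPM in 3 libraries), a block by replicate number, only the groups compared, all 15 libraries, and leaving out each library. Added after seeing the data were fits without KO NSD 1 and 3, without WT HSD 3 and WT NSD 3, without KO HSD 1, KO NSD 1 and KO NSD 3, with the effective length offset as a covariate, with 9 wild-type libraries pooled, a block within the wild type alone, and camera without each library in turn. Deviations from the group means correlated between libraries with the same number at r = 0.189, 0.108 and 0.484 across genes for wild type on the 2 diets, all above 0.1, so the numbers were taken to pair the samples there. Replicate 2 correlated more with another number (0.398). In the other contrasts they did not pair.

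FPKM and expected counts of 242 genes gave each gene's effective length as an indicator of library preparation. Each library's offset from the mean was computed. WT HSD 3, WT NSD 3 and both high salt libraries of the additional set lay between -3.71 and -2.79 nt, and all other libraries above -2 nt. This split is balanced over diet in the main wild type, not over genotype (no labelled knockout below -2 nt), and coincides with diet in the additional set. Counts of replicates were compared by chi-square over genes; no pair of the 13 within groups was identical, with 34.8 to 314 per degree of freedom.

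The fit was tested on simulated counts drawn from the real means and library sizes. Among genes changed 2-fold, 31.6% were recovered for the salt effect in wild type (12907 genes), 43.9% for the salt effect in the knockout (12863), 30.6% for the genotype effect on normal salt (12874) and 27.6% for that on high salt (12910). Of genes changed 4-fold, 83%, 89%, 80% and 88.9% were recovered in the same order, with 8, 7, 3 and 6 false calls. In the camera test, 8 of 100 random lists had p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the remaining steps.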

Results

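Gene expression was measured in the livers of wild-type mice and of mice labelled Sirt3 knockout, fed a high salt (8% NaCl) or a normal salt diet (0.4% NaCl), with 3 libraries in each of the 4 groups. A further 3 wild-type libraries formed an additional set, 2 on high salt and 1 on normal salt. Total expected counts ranged from 15726897 (WT NSD 3) to 19539406 (KO NSD 2) per library, and 12213 to 13015 genes per library had at least 10 counts. By the study's title, the questions were whether salt brings on an inflammatory response in the liver and whether SIRT3, a mitochondrial deacetylase, takes part in it. Across the 13051 genes tested, the biological coefficient of variation was 0.272.

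Sirt3 transcript was present in all groups, the labelled knockouts included. Sirt3 (Entrez ID 64384, GRCm38 chromosome 7, 140863663 to 140882309) stood at 51.0 ± 1.8 CPM in WT NSD and 49.9 ± 12.3 CPM in KO NSD (SD, n = 3 each). On high salt it stood at 70.6 ± 10.2 CPM in WT HSD and 61.6 ± 5.9 CPM in KO HSD. Labelled knockout against wild type, its log2 fold change was -0.03 ± 0.18 (SE) on normal salt (adjusted p = 0.969) and -0.20 on high salt (adjusted p = 1), by edgeR. Single libraries had 64.8, 43.4 and 43.8 CPM in KO NSD, 62.6, 68.8 and 56.7 CPM in KO HSD, 49.8, 52.8 and 53.2 CPM in WT NSD, and 83.9, 65.7 and 65.8 CPM in WT HSD. The additional set had 48.8 and 47.4 CPM on high salt and 74.1 CPM on normal salt. Without KO NSD 2 or without KO NSD 3 the log2 fold change on normal salt was 0.07 or 0.05. Since the count of the targeted gene does not set the libraries apart, they are called labelled knockout throughout, and every direction between genotypes rests on the labels.

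Transcripts of the Y chromosome were nearly absent from 2 of the libraries labelled male, KO NSD 1 and KO NSD 3. Ddx3y, an RNA helicase gene, had 4 and 0 counts there and 381 to 936 counts in the other 13 libraries. Kdm5d had 1 and 0 counts against 121 to 298, Eif2s3y 18 and 11 against 478 to 870, and Uty 29 and 26 against 124 to 298. Female-biased liver genes were high in the same 2 libraries. Sult2a1, a sulfotransferase gene, stood at 130 and 271 CPM in them, at 0.055 CPM in KO NSD 2 and at 0 in the 12 libraries outside KO NSD. KO HSD 1 carried Y-linked transcripts and had 47.4 CPM of Cyp2a4, a female-biased P450 gene.

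**Figure D1:**
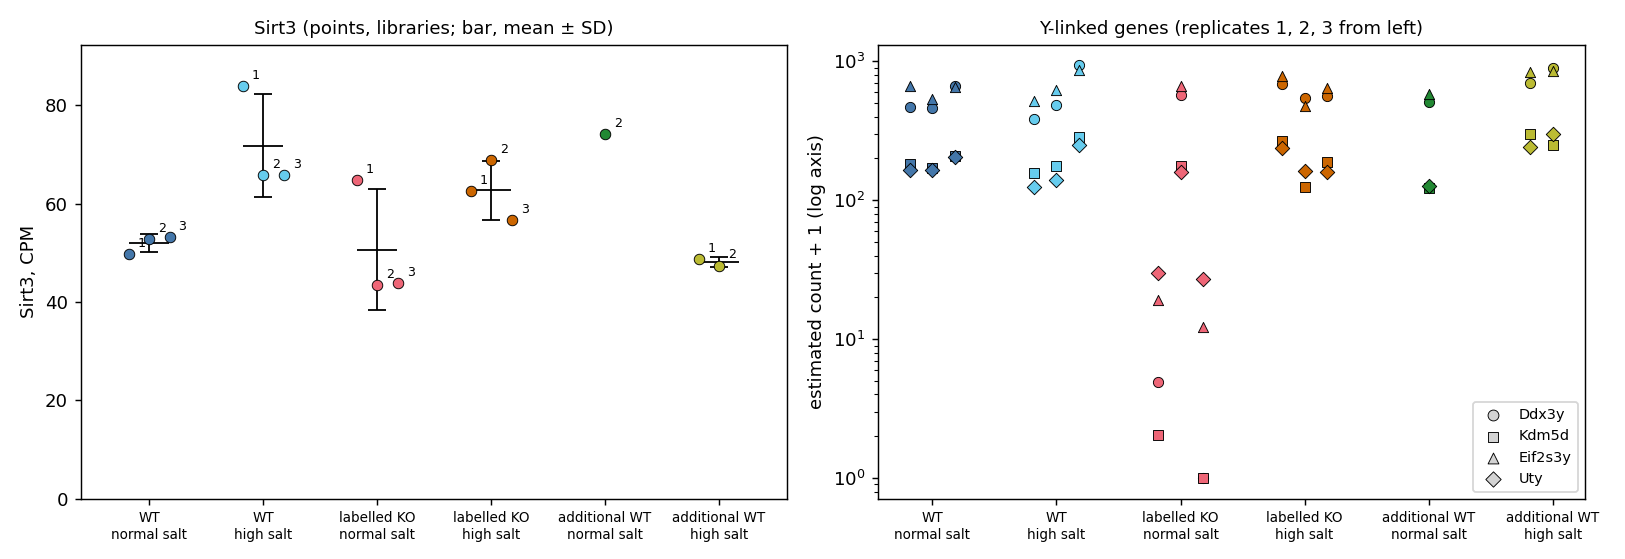
Left, Sirt3 in CPM (scaled over all 15 libraries) per library, with group means and SD, from 43.4 CPM (KO NSD 2) to 83.9 CPM (WT HSD 1). Right, counts of 4 Y-linked genes per library; KO NSD 1 and KO NSD 3 hold 0 to 29 counts of each.

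In the main wild-type set, high salt went with lower interferon-response, cholesterol synthesis, lipogenesis, neutrophil and acute phase genes. Clock output and proliferation genes were higher, but no single gene passed. All 25 interferon-response genes were lower (median log2 fold change -0.976, camera adjusted p = 3.08e-13, adjusted p = 0.71 with an estimated correlation). Among them were Oasl1, an antiviral gene (29.6 ± 17.6 to 12.1 ± 3.9 CPM), and Irgm1, a GTPase gene (70.8 ± 27.5 to 37.5 ± 9.1 CPM). Of 22 cholesterol synthesis genes, 21 were lower (median -0.736, adjusted p = 3.48e-10, adjusted p = 0.857 with an estimated correlation). Dhcr7, which makes cholesterol, went from 145 ± 13 to 72.7 ± 4.5 CPM, and Insig1, a sterol sensor, from 503 ± 115 to 264 ± 67 CPM. In the additional set Oasl1, Irgm1, Dhcr7 and Insig1 stood at -0.05, 1.61, -0.46 and 1.06 (none called). Of 18 lipogenesis genes 13 were lower (median -0.31, adjusted p = 0.000252, adjusted p = 0.71 with an estimated correlation). Acss2 and Acly, 2 sources of acetyl-CoA, stood at -1.03 and -0.84. For each of these lists 0 members passed adjusted over the list alone, and 0 over all genes. The interferon list rested largely on WT NSD 1, whose mean level was 1.148 against -0.643 and 0.011 in the other normal salt libraries. Without it the median was -0.243 (adjusted p = 0.0245, adjusted p = 0.986 with an estimated correlation). The lipogenesis median was -0.202 without WT HSD 1 (adjusted p = 0.0416) and -0.55 without WT HSD 3 (0.00282).

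No inflammatory list was called higher in the wild type on high salt with all 12 libraries and no block. MHC class II genes (median 0.382, adjusted p = 0.155) were called higher in the 6 wild-type libraries with a replicate block and without KO NSD 2 (adjusted p = 0.0282 each), with adjusted p = 0.806 and 0.76 with an estimated correlation. Acute phase proteins, made in inflammation, were lower in 24 of 27 (median -0.267, camera adjusted p = 0.001, adjusted p = 0.944 with an estimated correlation). Saa1 stood at 338 ± 492 CPM on normal and 41.7 ± 8.0 CPM on high salt and haptoglobin (Hp) at 3615 ± 1293 and 2178 ± 368 CPM. In the additional set their log2 fold changes were 2.05 and 0.66, not called. Without WT HSD 3 and WT NSD 3 this list was not called (adjusted p = 0.441). Neutrophil markers were lower in 11 of 13 genes (median -1.08, adjusted p = 0.000581, adjusted p = 0.944 with an estimated correlation). The list of inflammatory cytokines and NF-kB targets did not pass (median -0.05, mean 0.113, adjusted p = 0.852). Cxcl1, a neutrophil chemokine, stood at -1.91 and Tnf at 1.26. The NOD-like receptor and pyroptosis list did not pass either (median -0.111, mean 0.047, adjusted p = 0.852). Kupffer cell (liver macrophage) markers lay at a median of 0.315 (adjusted p = 0.157) and those of T and NK cells at -0.42 (adjusted p = 0.385). The acute phase list was not called without WT NSD 3 (-0.185, adjusted p = 0.347) and stood at -0.159 without WT HSD 1 (0.0416). Neutrophil markers were not called without WT NSD 1 (-0.657, adjusted p = 0.0556) or WT HSD 3 (-0.925, 0.185). Kupffer cell markers were called higher without WT HSD 2 (0.462, adjusted p = 0.0422) or WT HSD 3 (0.527, 0.0406), with adjusted p = 0.957 and 0.929 with an estimated correlation. None of these lists had a member past the threshold, over the list alone or all genes.

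Clock genes were called as a list between the diets in wild type. Of 19 clock genes 14 were higher on high salt (median 0.785, camera adjusted p = 4.11e-05, adjusted p = 0.39 with an estimated correlation), and 5 higher and 2 lower passed adjusted over the list alone, against 0 over all genes. Without WT NSD 3 the median was 1.44 and the list passed with an estimated correlation as well (adjusted p = 0.0206). Dbp, a clock-driven transcription factor gene, went from 6.67 ± 9.71 to 156 ± 125 CPM, with wide spread, and Tef from 38.9 ± 32.1 to 137 ± 55 CPM. All 14 proliferation genes were higher (median 0.803, adjusted p = 0.000118, adjusted p = 0.857 with an estimated correlation; 0 adjusted over the list alone). This list rested on WT HSD 1, with a mean level of 1.435 against 0.376 and -0.496 in the other high salt libraries; without it the median was 0.13 (adjusted p = 0.344). Fatty acid oxidation genes did not pass as a list (median 0.174, adjusted p = 0.121), though they did without WT NSD 3 (0.0346), WT HSD 3 (0.046) or WT HSD 2 (0.000198), with adjusted p = 0.929 to 0.954 with an estimated correlation. SIRT3 substrates (median 0.068, adjusted p = 0.298) and antioxidant genes (median -0.083, adjusted p = 0.816) did not pass either.

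By edgeR, 0 of 13051 genes passed between the diets in wild type (584 had an unadjusted p under 0.05 and the smallest adjusted p was 0.796), while DESeq2 called 9 (4 higher, 5 lower) and limma-voom 56 (12 higher, 44 lower). The smallest p belonged to Rapgef4, a cAMP-regulated exchange factor gene (Entrez ID 56508, GRCm38 chromosome 2, 71981215 to 72257474). It stood at 64.0 ± 8.3 CPM on normal and 154 ± 23 CPM on high salt (log2 fold change 1.27 ± 0.22 SE, adjusted p = 0.796). Aqp8, a water channel gene, stood at 171 ± 60 and 58.0 ± 21.1 CPM (adjusted p = 0.796). Sirt3 itself had a log2 fold change of 0.47 ± 0.18 (adjusted p = 1). Leaving out WT HSD 3, WT NSD 3 or WT HSD 1 gave 10, 3 and 1 genes, and leaving out WT HSD 3 and WT NSD 3 together gave 30 (7 higher, 23 lower). With the 6 wild-type libraries alone and a replicate block, 1 gene passed and 11 lists instead of 7; gluconeogenesis and fasting genes (adjusted p = 6.7e-08, lower), MHC class II (0.0282, higher), sinusoidal endothelial (0.0483, higher) and erythroid markers (0.0483, higher) joined the calls, each with adjusted p = 0.806 with an estimated correlation. The block in the fit of 12 libraries added gluconeogenesis (adjusted p = 0.043) and immediate early genes (0.0459), both lower and with adjusted p = 0.919 with an estimated correlation.

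The salt effects of the main and the additional wild-type set did not go together across genes. Across genes, which are not independent replicates, the log2 fold changes of the sets correlated at r = -0.075 (rho = -0.231). Single libraries turn that sign: r was 0.027, 0.028 and 0.082 without WT HSD 1, WT HSD 2 and WT NSD 3, and -0.28 without WT HSD 3. Of 624 genes with an unadjusted p under 0.05 in the main set, 172 (27.6%) had the same sign in the additional set. In the latter 3 genes passed, all lower on high salt, with 1673 at an unadjusted p under 0.05. They were Cfd, the adipocyte protease adipsin (log2 fold change -9.03 ± 1.04, adjusted p = 0.0192), Cidea, a lipid droplet protein gene (-7.80 ± 0.98, adjusted p = 0.0192), and Miox, an inositol oxygenase gene (-10.2 ± 1.2, adjusted p = 0.0184). These calls rest on the single normal salt library, in which Cfd stood at 52.1 CPM, against 0.186 and 0 CPM in the high salt libraries and 0.601 to 2.17 CPM in WT NSD. DESeq2 called 30 genes there (15 higher, 15 lower), and without either high salt library none of the 3 genes passed by edgeR (adjusted p = 0.118 to 0.321). The 1 call there was another gene each time, Gm14288 without the first (-9, adjusted p = 0.0458) and Irf1 without the second, higher on high salt (2.30, adjusted p = 0.0267). In that set the diet coincides with the split of the libraries by effective length, so the diet and that split cannot be told apart there.

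On normal salt, livers labelled Sirt3 knockout had higher levels of neutrophil and macrophage genes and lower levels of genes such as Sucnr1 and Coq8a than wild-type livers. Higher were S100a9, which codes for an abundant calcium-binding protein of neutrophils (1.89 ± 1.22 CPM in WT NSD, 38.0 ± 20.5 CPM in KO NSD; 20.0-fold, adjusted p = 0.0353), and Retnlg, a resistin-like gene of neutrophils (13.8-fold, log2 fold change 3.79 ± 0.48, adjusted p = 0.00784). So were Itgam, the CD11b integrin of myeloid cells (5.18-fold, 2.37 ± 0.31, adjusted p = 0.00784), Fcgr4, an IgG receptor (2.39 ± 0.42 to 11.3 ± 2.9 CPM, adjusted p = 0.0237), and Pla2g7, a secreted phospholipase of macrophages (9.43-fold, adjusted p = 0.00929). The formyl peptide receptor gene Fpr1, Pglyrp1, Chil3 and Arhgap9 rose 4.03- to 13.2-fold (adjusted p = 0.0237 to 0.0307). Lower were Sucnr1, the succinate receptor (54.1 ± 12.1 to 14.5 ± 2.2 CPM, log2 fold change -1.90 ± 0.22, adjusted p = 0.00784), and Coq8a, needed for coenzyme Q synthesis (495 ± 110 to 147 ± 34 CPM, adjusted p = 0.0237). Lower as well were Rnf125, a ubiquitin ligase (393 ± 113 to 65.6 ± 7.4 CPM, adjusted p = 0.0237), and Mapk15, an atypical MAP kinase (33.4 ± 8.3 to 4.52 ± 0.69 CPM, adjusted p = 0.00806). The smallest p belonged to the zinc finger gene Zfp991 (Entrez ID 666532, GRCm38 chromosome 4, 147132093 to 147180579). It stood at 9.77 ± 2.63 and 0.937 ± 0.064 CPM (-3.37 ± 0.31, adjusted p = 0.000955). Its neighbour Zfp992 stood at -2.47 ± 0.31 (adjusted p = 0.00784). Without WT NSD 1 or WT NSD 2, 0 higher genes passed by edgeR (6 and 5 lower; 1647 and 1541 with an unadjusted p under 0.05). S100a9 then stood at log2 fold changes of 4.96 and 4.19 (adjusted p = 0.105 and 0.154) against 4.32.

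Immune cell lists followed. Of 13 neutrophil markers 12 were higher (median log2 fold change 4.32, camera adjusted p = 3.31e-19, adjusted p = 0.278 with an estimated correlation). Over all genes 5 of them rose, S100a8 (1.41 ± 0.46 to 31.6 ± 18.6 CPM) and the collagenase gene Mmp8 included, and 11 adjusted over the list alone. Of 16 Kupffer cell and macrophage markers 15 were higher (median 1.78, adjusted p = 6.15e-16, adjusted p = 0.317 with an estimated correlation), with 1 past the threshold over all genes and 13 adjusted over the list alone. Csf1r, the receptor macrophages need for survival, stood at 21.3 ± 3.6 and 75.3 ± 32 CPM (adjusted p = 0.0738), Cd68 at 2.00 and Lyz2 at 1.84. Inflammatory cytokines and NF-kB targets were higher in 21 of 24 genes (median 0.849, adjusted p = 1.29e-07, adjusted p = 0.317 with an estimated correlation; 10 adjusted over the list alone, 0 over all genes). Tnf stood at 3.05 (adjusted p = 0.0513), Nlrp3, the inflammasome sensor, at 2.17 and the adhesion gene Vcam1 at 1.12. T and NK cell markers were higher in 12 of 14 (median 1.37, adjusted p = 1e-06, adjusted p = 0.317 with an estimated correlation; 10 higher and 1 lower adjusted over the list alone, 0 over all genes). All 7 MHC class II genes were higher (median 1.18, adjusted p = 2.68e-05, adjusted p = 0.335 with an estimated correlation; 7 adjusted over the list alone, 0 over all genes). Acute phase genes were higher in 20 of 27 (median 0.454, adjusted p = 0.00514, adjusted p = 0.759 with an estimated correlation). B and plasma cell markers were higher (0.913, adjusted p = 0.015, adjusted p = 0.462 with an estimated correlation). The same held for sinusoidal endothelial markers (0.459, adjusted p = 0.0102; adjusted p = 0.753 with an estimated correlation) and NOD-like receptor genes (0.411, adjusted p = 0.0444; adjusted p = 0.682 with an estimated correlation; 2 adjusted over the list alone). In the acute phase, B cell and endothelial lists 0 members passed adjusted over the list alone. With the replicate block, the NOD-like receptor list no longer passed (adjusted p = 0.0612). Nor was it called without WT NSD 2 (0.49, adjusted p = 0.0586) or KO NSD 1 (0.15, 0.31), while its median was 0.81 without KO NSD 2 and 0.68 without WT NSD 1. Calls also ended for acute phase genes without WT NSD 1 (adjusted p = 0.151) or KO NSD 1 (0.165), for B and plasma cell markers without WT NSD 3 (0.139) or KO NSD 3 (0.134) and for sinusoidal endothelial markers without WT NSD 1 (0.162) or KO NSD 3 (0.321; 0.764 as the median without WT NSD 2). The inflammatory cytokine median was 0.432 without KO NSD 1 (adjusted p = 0.00104). When KO NSD 1 and KO NSD 3, which lack Y-linked transcripts, were left out, MHC class II genes turned direction (adjusted p = 0.929), and inflammatory cytokines (0.172), NOD-like receptor genes (0.967) and sinusoidal endothelial markers (0.962) lost their calls. KO NSD 2 then stands alone and is assumed to vary like the other groups, so the values are the level of 1 library. Neutrophil markers had a median of 3.42 (adjusted p = 2.08e-15, adjusted p = 0.182 with an estimated correlation). The Kupffer cell and T and NK cell medians went down to 0.555 (adjusted p = 0.000313) and 0.613 (0.0494), each with adjusted p = 0.645 with an estimated correlation.

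**Figure D2:**
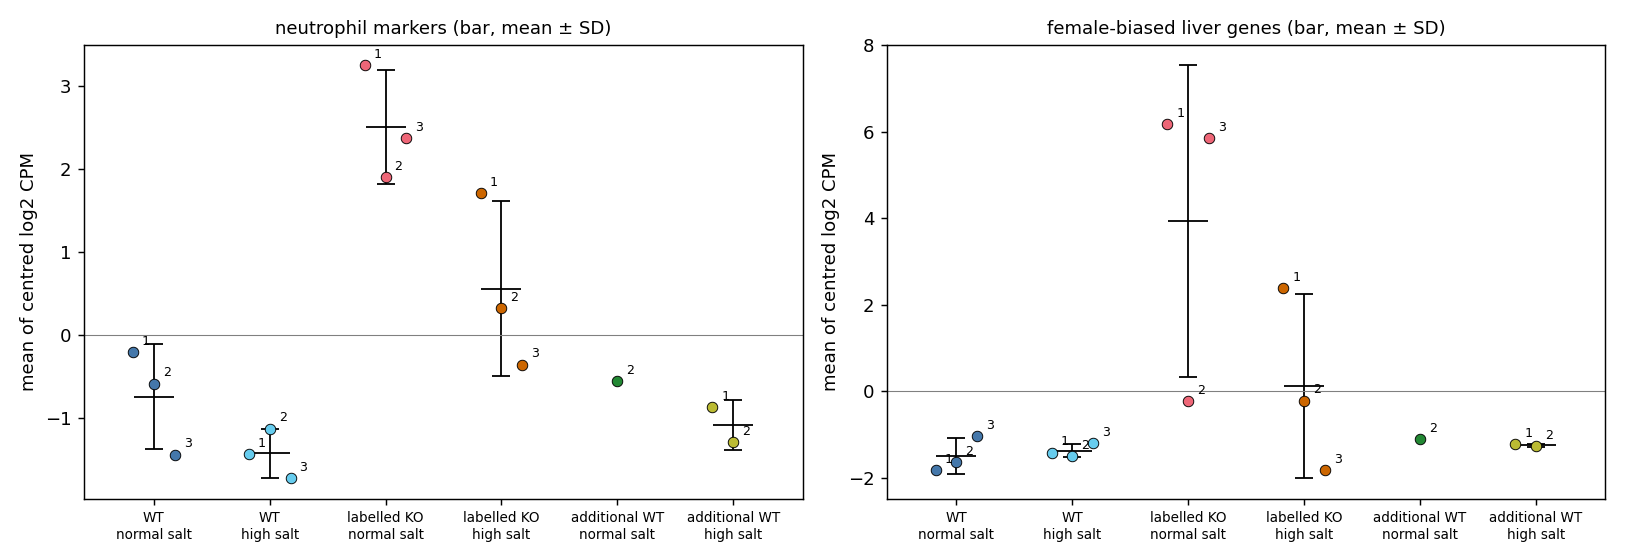
Mean log2 level of the members of gene lists per library, centred over the 15 libraries, with replicate numbers beside the points and bars for mean and SD. Left, neutrophil markers; right, female-biased liver genes. Neutrophil markers lie highest in KO NSD 1 (3.25) and female-biased genes in KO NSD 1 and KO NSD 3 (6.17 and 5.84).

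Sex-biased liver genes stood out in the same comparison, with the libraries that lack Y-linked transcripts. All 20 male-biased genes were lower (median -2.73, camera adjusted p = 1.95e-16, adjusted p = 0.317 with an estimated correlation), with 1 past the threshold over all genes and 4 adjusted over the list alone. The complement gene C8a fell (693 ± 83 to 340 ± 86 CPM, adjusted p = 0.0466), and the fatty acid elongase gene Elovl3 stood at 504 ± 315 and 2.00 ± 2.18 CPM (adjusted p = 0.0734). All 14 female-biased genes tested were higher (median 7.03, adjusted p = 2.39e-11, adjusted p = 0.317 with an estimated correlation; 12 adjusted over the list alone, 0 over all genes). Cyp17a1, a steroid hydroxylase gene, stood at 4.29 ± 1.69 and 89.0 ± 15.0 CPM (adjusted p = 0.0539). Clock genes were higher in 14 of 19 (median 0.916, adjusted p = 0.0062, adjusted p = 0.317 with an estimated correlation; 7 higher and 2 lower adjusted over the list alone). The clock list was not called without WT NSD 1 (adjusted p = 0.0528), and its median was 0.566 without KO NSD 1 and 0.531 without WT NSD 2. Lipogenesis genes were lower in 13 of 18 (median -0.327, adjusted p = 0.00107, adjusted p = 0.335 with an estimated correlation; 5 lower adjusted over the list alone). Without KO NSD 2 the medians of the lipogenesis, male-biased and female-biased lists were -0.52, -6.11 and 8.07, and the last passed with an estimated correlation (adjusted p = 0.0424). With KO NSD 2 alone in the group, male-biased genes stood at -1.24 and female-biased at 1.71. SIRT3 substrates (median -0.102, adjusted p = 0.504) did not pass. The same held for fatty acid oxidation (0.219, adjusted p = 0.504), which was called higher without KO NSD 1 (0.0086; adjusted p = 0.622 with an estimated correlation), and antioxidant genes (-0.085, adjusted p = 0.355).

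By edgeR, 54 genes passed (31 higher, 23 lower in the labelled knockout; 1860 with an unadjusted p under 0.05), 52 of them with an absolute log2 fold change of at least 1. Upper-quartile scaling gave 16 higher and 19 lower, DESeq2 661 genes, limma-voom 1604 and the replicate block, whose numbers do not pair here, 98. Without KO NSD 1 and KO NSD 3, which leaves 1 library in the group, all 54 kept their direction. Without WT HSD 3 and WT NSD 3 the balance of directions turned, with 74 genes (18 higher, 56 lower), 26 of them shared with the 54. Higher and lower genes numbered 0 and 5 without WT NSD 2, 0 and 6 without WT NSD 1, 9 and 26 without WT NSD 3, 4 and 7 without KO NSD 1, 329 and 91 without KO NSD 2 and 5 and 7 without KO NSD 3. They were 13 and 12 without WT HSD 1, 7 and 10 without WT HSD 2, 62 and 78 without WT HSD 3 and 58 and 29 without KO HSD 3. These fits kept all 54 directions but test little, since the same libraries chose them.

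On high salt, acute phase and neutrophil genes were higher in the labelled knockout than in wild type, and cholesterol synthesis genes with them, but no single gene passed the test. Of 27 acute phase genes 26 were higher (median log2 fold change 1.04, camera adjusted p = 3.1e-21, adjusted p = 0.253 with an estimated correlation), 10 of them adjusted over the list alone and 0 over all genes. Hp stood at 2178 ± 368 and 6158 ± 2484 CPM and hemopexin (Hpx) at 4342 ± 944 and 9472 ± 3973 CPM. All 13 neutrophil markers were higher (median 3.34, adjusted p = 1.98e-22, adjusted p = 0.192 with an estimated correlation; 11 adjusted over the list alone, 0 over all genes). S100a9 stood at 0.920 ± 0.275 and 9.54 ± 7.40 CPM. T and NK cell markers were higher in 12 of 14 (median 1.12, adjusted p = 7.41e-08, adjusted p = 0.253 with an estimated correlation; 5 adjusted over the list alone). Inflammatory cytokines (median 0.331, adjusted p = 0.000315; adjusted p = 0.517 with an estimated correlation) were higher as well. So were Kupffer cell markers (0.34, adjusted p = 0.00224; adjusted p = 0.573 with an estimated correlation) and interferon-response genes (0.242, adjusted p = 0.00202; adjusted p = 0.598 with an estimated correlation), and in these 3 lists 0 members passed adjusted over the list alone. Without WT HSD 3 and WT NSD 3 the Kupffer cell list did not pass (adjusted p = 0.229). The same list was not called without WT HSD 2 (adjusted p = 0.133), WT HSD 3 (0.216) or KO HSD 2 (0.958, median -0.138), and its median was 0.546 without KO HSD 3 and 0.736 without WT HSD 1. The interferon-response list was not called without WT HSD 2 (adjusted p = 0.061, with a like median of 0.244) or KO HSD 1 (0.12, adjusted p = 0.13), with a median of 0.477 without WT HSD 1. Medians were 2.02 for neutrophil markers without KO HSD 1 (adjusted p = 2.12e-17) and 0.48 for T and NK cell markers without KO HSD 3 (0.00192). The NOD-like receptor list did not pass (0.11, adjusted p = 0.0703) except without WT HSD 1 (0.0118), KO HSD 3 (0.0294), WT NSD 1 (0.044) or any 1 of KO NSD 1 to 3 (0.0333, 0.037 and 0.0472), with adjusted p = 0.347 to 0.629 with an estimated correlation.

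Metabolic lists also differed between the labelled genotypes on high salt. All 22 cholesterol synthesis genes were higher (median 0.664, camera adjusted p = 7.41e-08, adjusted p = 0.517 with an estimated correlation). Gluconeogenesis and fasting genes were higher in 11 of 13 (median 0.849, adjusted p = 1.97e-06, adjusted p = 0.253 with an estimated correlation; 3 adjusted over the list alone). Igfbp1, an insulin-repressed gene, stood at 17.8 ± 7.6 and 142 ± 80 CPM. Fatty acid oxidation genes were lower in 24 of 25 (median -0.303, adjusted p = 3.81e-05, adjusted p = 0.517 with an estimated correlation). Antioxidant genes were lower in 15 of 19 (median -0.277, adjusted p = 0.000886, adjusted p = 0.253 with an estimated correlation; 1 lower adjusted over the list alone). SIRT3 substrates lay at -0.141 (adjusted p = 0.0631) and were called without KO HSD 1 (0.00983) or WT HSD 3 (0.0407), with adjusted p = 0.515 and 0.504 with an estimated correlation. Without WT HSD 1 neither fatty acid oxidation (-0.095, adjusted p = 0.322) nor antioxidant genes (-0.079, 0.0958) were called. Without KO HSD 3 their medians were -0.465 and -0.121 and that of cholesterol synthesis 0.314 (adjusted p = 0.0274). Without KO HSD 1 antioxidant genes stood at -0.157 and gluconeogenesis genes at 0.265 (adjusted p = 0.000948).

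Cell type, sex-biased and regulatory lists differed on high salt as well, several through 1 library. Stellate cell and matrix genes (median -0.456) and sinusoidal endothelial markers (-0.421) were lower, each with adjusted p = 3.81e-05 and adjusted p = 0.517 with an estimated correlation. Both lists rested largely on KO HSD 1, and without it neither was called (-0.184, adjusted p = 0.0671, and -0.086, adjusted p = 0.295). The stellate median was -0.29 without WT HSD 2 and the endothelial -0.65 without KO HSD 3. Male-biased genes were lower (-0.913, adjusted p = 3.81e-05; adjusted p = 0.568 with an estimated correlation) and female-biased genes higher (2.47, adjusted p = 4.85e-05; adjusted p = 0.517 with an estimated correlation). In KO HSD 1, Cyp2a4 reached 47.4 CPM, against a mean of 0.0306 CPM in WT HSD, and without it neither male-biased (-0.384, adjusted p = 0.169) nor female-biased genes (0.586, 0.494) were called. The male-biased median was -0.571, -2.84 and -0.457 without KO HSD 2, KO HSD 3 and WT HSD 1. All 15 immediate early genes were higher (median 0.481, adjusted p = 0.00023, adjusted p = 0.384 with an estimated correlation), but not called without WT HSD 2 (0.082, adjusted p = 0.142), with medians of 0.179 without KO HSD 3 and 1.02 without WT HSD 1. Also higher were glucocorticoid targets in 12 of 14 (0.284, adjusted p = 0.00575, adjusted p = 0.517 with an estimated correlation) and complement genes in 17 of 22 (0.157, adjusted p = 0.0115, adjusted p = 0.517 with an estimated correlation). Glucocorticoid targets were not called without WT HSD 2 (adjusted p = 0.26), KO HSD 1 (0.13) or KO HSD 2 (0.0947), with medians of 0.444 to 0.483 without KO HSD 3, WT HSD 3 or WT HSD 1. The complement list was not called without WT HSD 3 and WT NSD 3 together (adjusted p = 0.11), nor without WT HSD 1 (0.0751), WT HSD 3 (0.1), KO HSD 1 (0.169) or KO HSD 2 (0.0625), where its medians were 0.169, 0.146, 0.103 and 0.141. Proliferation genes were lower in 13 of 14 (-0.455, adjusted p = 0.00418, adjusted p = 0.52 with an estimated correlation). This again rested on WT HSD 1, without which the median was -0.096 and the test pointed higher (adjusted p = 0.96). The call also ended without KO HSD 3 (-0.398, adjusted p = 0.142), and the median was -0.711, -0.742 and -0.922 without KO HSD 1, WT HSD 2 and WT HSD 3. In these last 4 lists 0 members passed adjusted over the list alone.

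By edgeR, 0 genes passed between the labelled genotypes on high salt (603 with an unadjusted p under 0.05, smallest adjusted p 0.221), as by limma-voom, while DESeq2 called 29 (21 higher, 8 lower). Leaving out KO HSD 3 gave 7 genes and leaving out WT HSD 1 gave 2. Genes with the smallest p were Zfp991 (6.83 ± 2.16 to 1.91 ± 0.18 CPM, adjusted p = 0.221), Sucnr1 (41.1 ± 3.8 to 16.5 ± 4.3 CPM, adjusted p = 0.221) and the peptide transporter gene Slc15a2 (-3.17) among those lower. Among those higher were Gm14326 (1.27 ± 0.20, adjusted p = 0.221) and Pisd, which makes phosphatidylethanolamine in mitochondria (78.6 ± 10.0 to 140 ± 6 CPM, adjusted p = 0.479). The genotype effects on the 2 diets share no library, but deviations of wild-type libraries with the same number correlate across the diets. That can add to a correlation of the effects. The genotype effects correlated across genes at r = 0.45 (rho = 0.299). On high salt, 50 of the 54 genes called on normal salt (92.6%) had the same sign. Without KO NSD 1 and KO NSD 3 the correlation was 0.261.

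**Figure D3:**
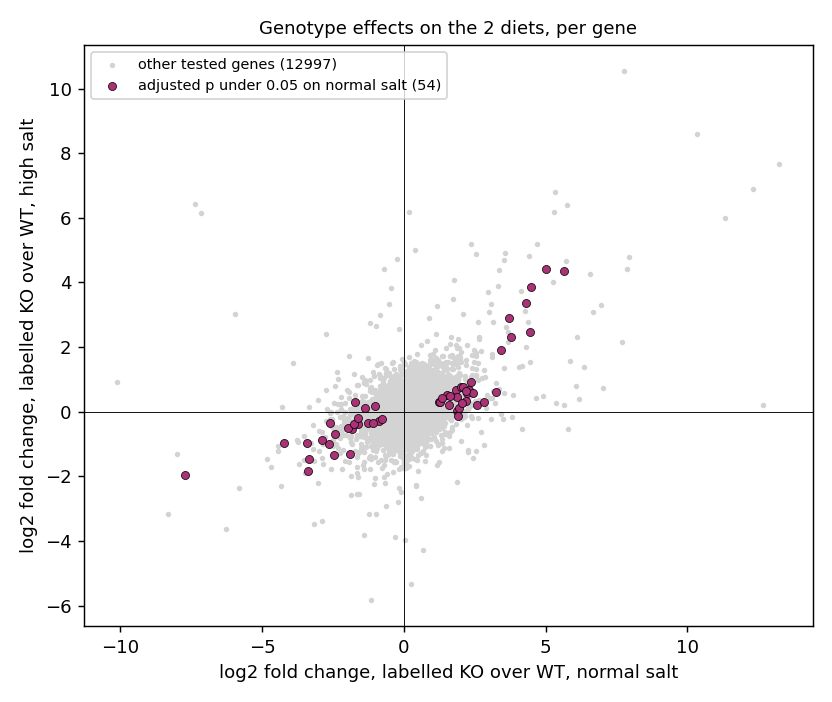
Each point is a gene; the axes give the log2 fold change, labelled knockout over wild type, on normal salt (horizontal) and on high salt (vertical). The 54 genes past the threshold on normal salt are drawn large and coloured, and 50 of them have the same sign on both axes.

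In the labelled knockout, high salt went with lower levels of immune, endothelial, stellate and female-biased genes and higher levels of male-biased, complement and bile acid genes, several of these calls resting on KO NSD 1 and KO NSD 3, and no single gene passed the test. Neutrophil markers were lower in 12 of 13 (median log2 fold change -1.99, camera adjusted p = 1.94e-11, adjusted p = 0.285 with an estimated correlation; 9 lower adjusted over the list alone, 0 over all genes). The granule protein gene Ngp stood at 37.4 ± 23.6 and 4.02 ± 5.44 CPM. Kupffer cell markers were lower in 15 of 16 (median -1.06, adjusted p = 3.93e-10, adjusted p = 0.35 with an estimated correlation; 1 adjusted over the list alone). Inflammatory cytokines were lower in 20 of 24 (-0.319, adjusted p = 0.000538; adjusted p = 0.457 with an estimated correlation). The same direction was found for B and plasma cell markers (-1.30, adjusted p = 1.11e-06; adjusted p = 0.285 with an estimated correlation). MHC class II genes (-0.554, adjusted p = 0.0083; adjusted p = 0.5 with an estimated correlation) and T and NK cell markers (-0.315, adjusted p = 0.0158; adjusted p = 0.5 with an estimated correlation) were lower. Sinusoidal endothelial markers (-0.709, adjusted p = 5.74e-08; adjusted p = 0.35 with an estimated correlation) were lower too. So were stellate cell genes (-0.547, adjusted p = 4.59e-05; adjusted p = 0.406 with an estimated correlation; Dcn 145 ± 30 to 71.1 ± 10.3 CPM) and cholangiocyte markers (-0.595, adjusted p = 0.00509; adjusted p = 0.35 with an estimated correlation). Acute phase genes (0.265, adjusted p = 0.224) and NOD-like receptor genes (-0.192, adjusted p = 0.388) did not pass, the former except without KO NSD 1 (0.00206) or KO HSD 3 (6.65e-07), with adjusted p = 0.635 and 0.373 with an estimated correlation. Inflammatory cytokines were not called without KO NSD 1 (-0.075, adjusted p = 0.482) but stood at -0.607 without KO HSD 3 (0.0065) and -0.526 without KO NSD 2 (5.1e-06). Cholangiocyte markers were not called without KO NSD 2 (-0.683, adjusted p = 0.0572) or KO HSD 1 (-0.449, 0.155). Calls of MHC class II genes and of T and NK cell markers ended without KO NSD 3 (0.123 and 0.189), KO NSD 1 (0.345 and 0.055) or KO HSD 1 (0.136 and 0.467). Without KO NSD 1 the Kupffer cell and stellate medians were -0.642 and -0.3, without KO HSD 1 the endothelial and stellate medians -0.398 and -0.334, and without KO NSD 3 the endothelial median -0.356. Other medians lay farther from 0 without KO HSD 3 (B cell -1.99, T and NK cell -0.826, cholangiocyte -1.21) or KO NSD 2 (MHC class II -0.926). With both KO NSD 1 and KO NSD 3 left out, calls ended for Kupffer cell (-0.021, adjusted p = 0.697) and sinusoidal endothelial markers (adjusted p = 0.131), the inflammatory, T and NK cell and stellate lists turned direction (adjusted p = 0.406, 0.559 and 0.518), and neutrophil markers stood at -1.08 (adjusted p = 0.000232; adjusted p = 0.422 with an estimated correlation). MHC class II genes were then called higher (adjusted p = 0.00381, adjusted p = 0.422 with an estimated correlation), with KO NSD 2 alone in its group and assumed to vary like the others.

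Sex-biased and metabolic lists in the labelled knockout moved in both directions on high salt. Male-biased genes were higher in 19 of 20 (median 1.92, camera adjusted p = 3.53e-12, adjusted p = 0.35 with an estimated correlation). All 14 female-biased genes were lower (median -2.80, adjusted p = 1.98e-08, adjusted p = 0.35 with an estimated correlation). Cyp3a41a stood at 1047 ± 931 and 0.429 ± 0.374 CPM. Complement and coagulation genes were higher in 20 of 22 (0.245, adjusted p = 2.33e-06; adjusted p = 0.299 with an estimated correlation), among them C8a (340 ± 86 to 776 ± 56 CPM, adjusted p = 0.303). Bile acid genes were higher in 13 of 16 (0.414, adjusted p = 2.67e-05; adjusted p = 0.107 with an estimated correlation; 2 adjusted over the list alone). Gluconeogenesis genes (0.253, adjusted p = 0.0282; adjusted p = 0.5 with an estimated correlation; G6pc 105 ± 90 to 401 ± 108 CPM) and immediate early genes (0.66, adjusted p = 0.0393; adjusted p = 0.5 with an estimated correlation) were higher. Fatty acid oxidation genes were lower in 18 of 25 (-0.222, adjusted p = 0.00385; adjusted p = 0.545 with an estimated correlation). SIRT3 substrates (0.014, mean -0.005, adjusted p = 0.693) and antioxidant genes (-0.192, adjusted p = 0.0831) did not pass, the latter except without KO NSD 1 (0.0205; adjusted p = 0.44 with an estimated correlation). Gluconeogenesis genes were not called without KO NSD 2 (0.166, adjusted p = 0.22), KO HSD 1 (0.09, 0.437) or WT HSD 3 (0.281, 0.0605), and stood at 0.47 without KO HSD 3. Immediate early genes were not called without KO NSD 2 (0.377, adjusted p = 0.421) or KO HSD 3 (0.387, 0.291), nor, with medians near that of all libraries, without KO HSD 2 (0.595, 0.0689), WT HSD 3 (0.687, 0.0789) or WT NSD 3 (0.688, 0.052). Fatty acid oxidation genes were not called without KO HSD 2 (-0.166, adjusted p = 0.108) or KO NSD 2 (-0.1, 0.184). Without KO NSD 2 the male-biased and female-biased medians were 4.97 and -4.45, and female-biased and bile acid genes passed with an estimated correlation as well (adjusted p = 0.00826 and 0.0455). With both KO NSD 1 and KO NSD 3 left out, neither male-biased (0.72, adjusted p = 0.7) nor female-biased genes (1.93 with a test pointing lower, 0.954) were called, and bile acid genes stood at 0.145 (0.0109). The male-biased median was 0.946 without KO HSD 3 and the female-biased -6.61 without KO HSD 1. Complement genes stood at 0.42 without KO NSD 1, and fatty acid oxidation genes at -0.399 without it and -0.139 without KO NSD 3.

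By edgeR, 0 genes passed between the diets in the labelled knockout (1051 with an unadjusted p under 0.05, smallest adjusted p 0.303), while DESeq2 called 50 (22 higher, 28 lower) and limma-voom 139 (64 higher, 75 lower). Wdfy1 (9.77 ± 0.75 to 22.5 ± 4.9 CPM), C5ar1, the complement C5a receptor gene (2.22 ± 0.51 to 0.471 ± 0.214 CPM), and C8a had the smallest p (adjusted p = 0.303). Leaving out KO NSD 2 gave 21 genes and leaving out KO HSD 1 gave 2. Without KO NSD 1 and KO NSD 3, 0 genes passed (673 with an unadjusted p under 0.05 by edgeR).

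**Figure D4:**
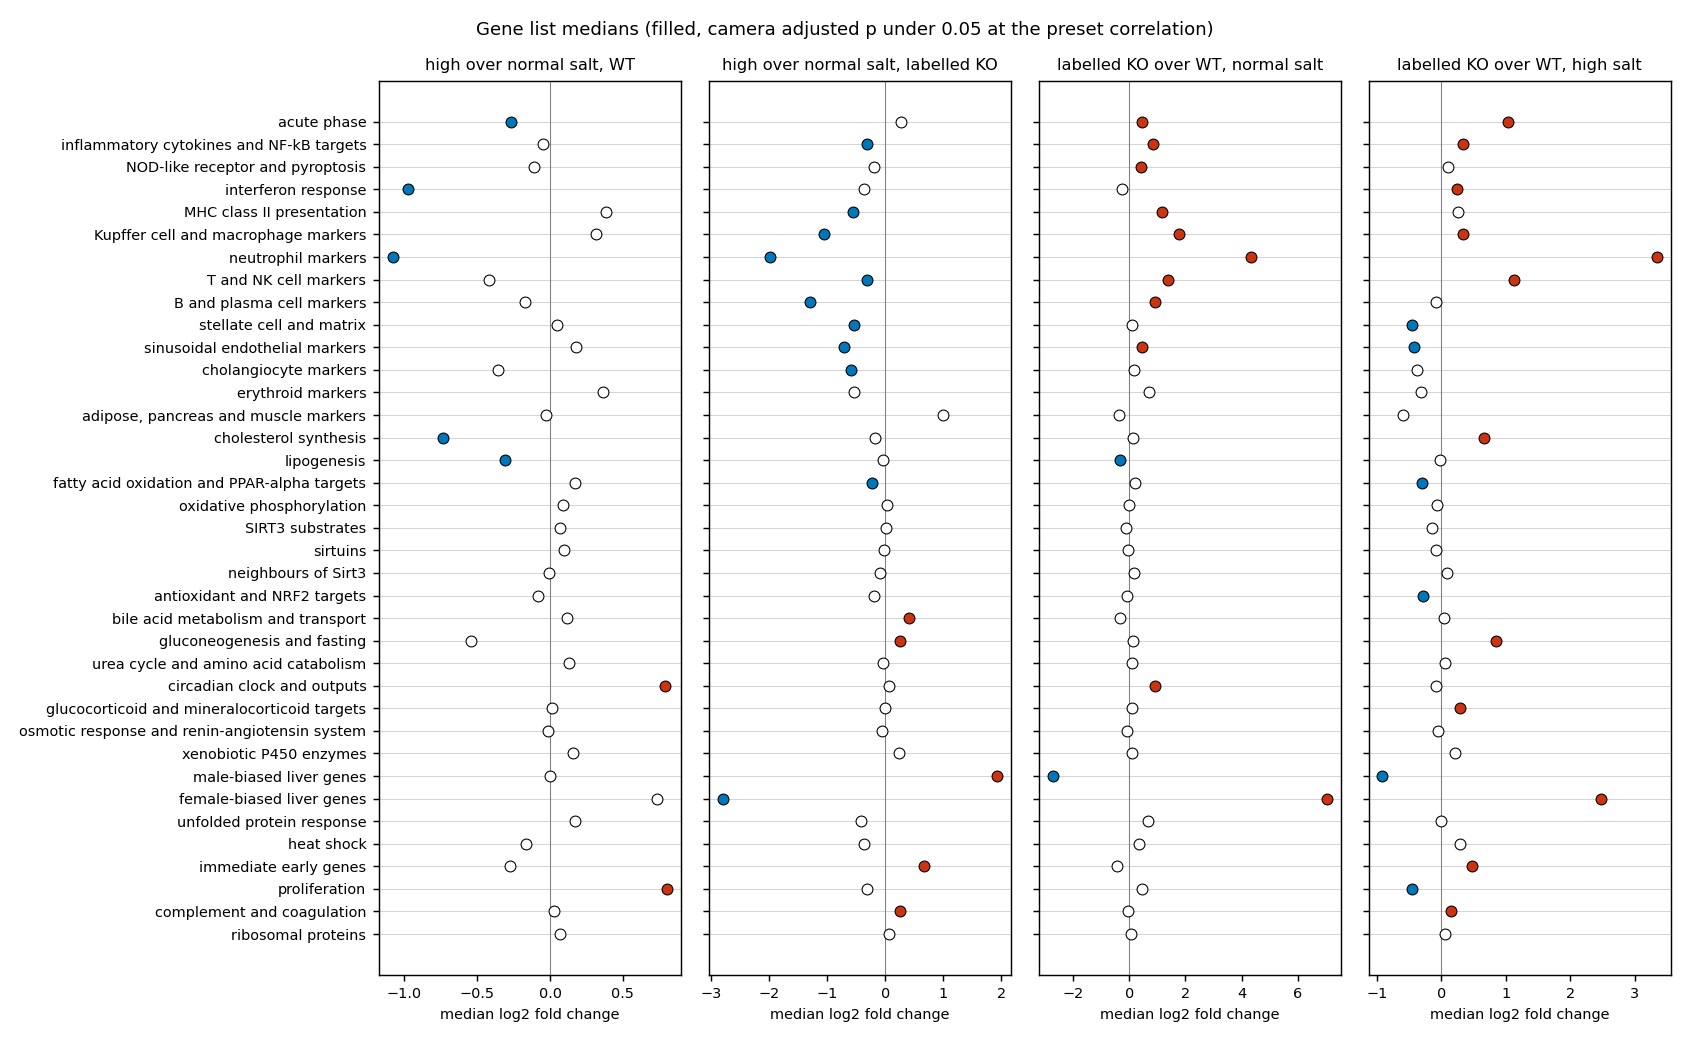
Median log2 fold change of the tested members of each of the 37 gene lists in 4 comparisons; filled points passed camera at the preset correlation with all 12 libraries, and none did with an estimated correlation.

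The interaction asked whether the salt effect differed between the labelled genotypes. Among the genes with the smallest p were Atg16l2 (2.03 ± 0.40) and the cardiac actin gene Actc1, for which salt effects were higher in the labelled knockout. For Pla2g7 (-2.63) and Limk1 (-1.54) they were lower, all 4 genes with adjusted p = 0.835. By edgeR, 0 genes passed (706 with an unadjusted p under 0.05), while DESeq2 called 10 (7 higher, 3 lower) and limma-voom 0. Leaving out KO NSD 2 gave 8 genes, WT HSD 3 gave 4, WT HSD 1, KO NSD 3 and WT NSD 3 gave 1 each, and leaving out WT HSD 3 and WT NSD 3 together gave 6. The salt effects of wild type and labelled knockout correlated across genes at r = -0.049 (rho = -0.006; 0.035 without KO NSD 1 and KO NSD 3). Camera called 21 lists, none of them with an estimated correlation (adjusted p = 0.466 to 0.592), and 13 of the 21 were not called without 1 or another single library, as for neutrophil markers without KO NSD 1 (adjusted p = 0.334). The salt effect in the labelled knockout, the genotype effect on normal salt and the interaction all use the KO NSD libraries.

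**Figure D5:**
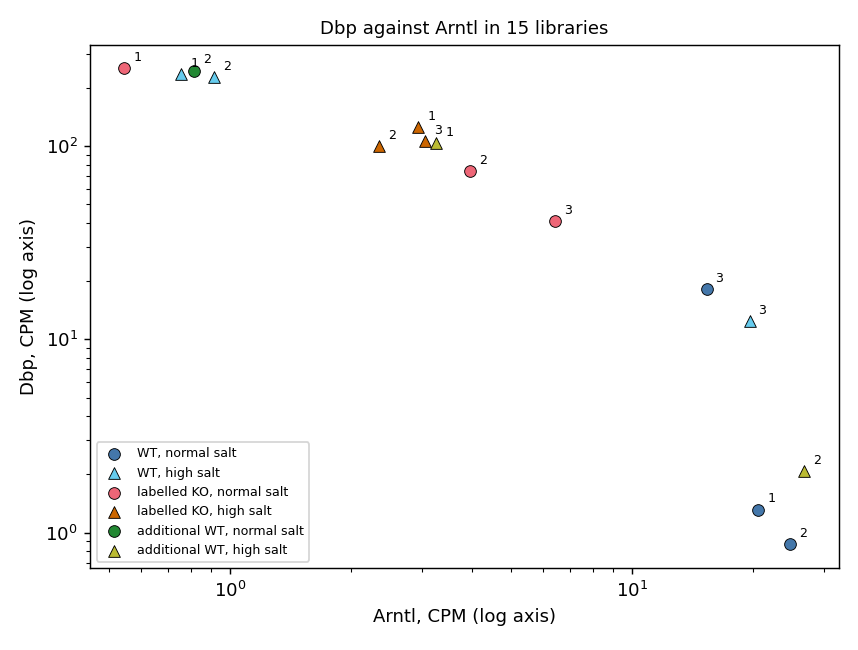
Dbp against Arntl in each of the 15 libraries, in CPM on log axes, with colours for the groups. Dbp runs from 0.868 to 253 CPM and Arntl from 0.547 to 26.9 CPM (rho = -0.946).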

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

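The tests of depth, of the labels, of the clock genes, of blood and of hepatocyte share, and the ranking of X-linked genes on one side of the effective length split, were chosen after the results were seen, as were the fits without KO NSD 1 and KO NSD 3 and the list tests without single libraries, whereas the ranking of X-linked genes among 15 libraries, that of neutrophil levels and the other splits were written down beforehand.

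Camera called 21 gene lists for a difference between the salt effects of the wild type and the labelled knockout at its preset correlation, and 0 with an estimated correlation (adjusted p = 0.466 to 0.592). Immune and vascular lists moved lower in the labelled knockout than in the wild type, with median log2 differences of -1.40 for Kupffer cell markers (camera adjusted p = 6.05e-09). They were -0.894 for sinusoidal endothelial markers (4.21e-08), -0.884 for MHC class II genes (0.00147) and -0.992 for B and plasma cell markers (0.00569). Differences were -0.669 for stellate cell genes (0.00108), -0.44 for inflammatory cytokines (0.00595), -0.626 for neutrophil markers (0.0401) and -0.908 for erythroid markers (0.0373). Lower too were fatty acid oxidation (-0.457, 0.000459), clock (-0.48, 0.0084), proliferation (-1.14, 0.00182) and female-biased genes (-4.20, 5.35e-07). Higher were acute phase (0.582, 0.00108), interferon-response (0.602, 0.00134), cholesterol synthesis (0.687, 0.000459), lipogenesis (0.35, 0.00182), bile acid (0.29, 0.02), and gluconeogenesis genes (0.803, 0.00211). Immediate early (1.17, 0.00182), complement (0.225, 0.00147) and male-biased genes (1.89, 6.05e-09) were higher too. Adjusted over the list alone, 2 gluconeogenesis genes, 1 complement gene and 1 male-biased gene passed, against 0 over all genes. Without KO NSD 1 and KO NSD 3, where KO NSD 2 stands alone and is assumed to vary like the other groups, 10 lists were called. The unfolded protein response was among them (median -0.87, adjusted p = 4.75e-12, and adjusted p = 0.0543 with an estimated correlation), which is the level of KO NSD 2 alone. The others were the acute phase, interferon, B cell, sinusoidal endothelial, erythroid, fatty acid oxidation, gluconeogenesis, immediate early and complement lists. The inflammatory (adjusted p = 0.495), MHC class II (0.38), stellate (0.711) and cholesterol synthesis (0.379) tests changed sign. Calls were lost for Kupffer cell (0.173), neutrophil (0.624; median 0.042, test pointing lower), lipogenesis (0.0841), bile acid (0.238), clock (0.0524), proliferation (0.537), male-biased (0.624) and female-biased lists (0.577; median 1.73, test pointing lower). Without single libraries 13 of the 21 calls ended at least once. The interferon test changed sign without WT NSD 1 (median -0.002, adjusted p = 0.904) and was not called without KO NSD 2 (0.137; median 0.934 without WT NSD 2). Neutrophil markers were not called without WT HSD 2 (0.286), KO HSD 2 (0.11), WT NSD 3 (0.397), KO HSD 3 (0.354) or KO NSD 1 (0.334) (median -1.40 without KO HSD 1). Erythroid markers were not called without WT HSD 1 (0.43), WT HSD 2 (0.235), WT NSD 3 (0.258), KO HSD 1 (0.0525), KO HSD 3 (0.0918), KO NSD 2 (0.178) or KO NSD 3 (0.0937), with medians of -0.69 to -1.035. Calls ended without WT HSD 1 for proliferation (0.204) and fatty acid oxidation (0.108), without WT HSD 2 for bile acid genes (0.0522; median 0.263) and without WT HSD 3 for clock genes (0.0779; median -0.706). They ended without WT NSD 3 for acute phase (0.104), bile acid (0.165) and gluconeogenesis genes (0.113), and without KO HSD 1 for acute phase (0.0869) and bile acid genes (0.0883; median 0.278). They ended without KO HSD 2 for lipogenesis (0.0527), without KO HSD 3 for cholesterol synthesis (0.0588), without KO NSD 1 for cholesterol synthesis (0.397) and inflammatory cytokines (0.564) and without KO NSD 2 for immediate early genes (0.0725). Medians of lists still called were, without KO HSD 3, -2.25 (B cell), 0.357 (complement), 0.547 (immediate early) and 0.785 (male-biased). Without KO HSD 1 they were -6.8 (female-biased), 0.275 (gluconeogenesis) and -0.551 (endothelial). Without KO NSD 1 they were -0.553 (MHC class II), 1.09 (acute phase), 0.427 (complement) and -0.276 (stellate), and without KO NSD 3 -0.66 (B cell) and -0.546 (endothelial). Without KO NSD 2 they were 1.1 (cholesterol synthesis), -0.687 (inflammatory), 0.526 (lipogenesis) and 5.45 (male-biased). Complement stood at 0.148 without WT HSD 1 and clock genes at -0.792 without WT NSD 3.

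Y-linked transcripts were nearly absent from KO NSD 1 and KO NSD 3, and female-biased liver genes were high in both. Low depth was argued against, since the lower of their totals was 0.985 times the median of the other 13 libraries, and so were the labelled genotype and diet, since KO NSD 2 held 571 counts of Ddx3y. If the RNA came from female mice, the X-linked genes that escape inactivation (Kdm6a, Eif2s3x, Kdm5c, Ddx3x) would be highest there. The lower of the 2 libraries ranked 6 of 15, below the fourth place set beforehand as the limit. That limit did not allow for the effective length split: the 4 libraries on its other side, all with Y-linked transcripts, ranked 1, 2, 3 and 5 and so took 3 of the first 4 places. Among the 11 libraries on their own side of the split the 2 ranked first and second (lower rank 2, out of 55 possible pairs), which is consistent with female mice, against their labels, as a hypothesis. Whether the labels or the animals were exchanged stays open.

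Dbp and Arntl, opposite arms of the clock, stood at opposite levels in the main wild-type groups on the 2 diets. Over the 15 libraries they were inversely related (r = -0.899, rho = -0.946, each with permutation p = 1e-05, the smallest 100000 permutations can give, adjusted p = 3e-05; r = -0.952 without the 2 farthest libraries). Of the 3 relations computed, that within high salt gave r = -0.95 (exact permutation, adjusted p = 0.00149; -0.896 without the 2 farthest) and rho = -0.786 (adjusted p = 0.0279), and that within normal salt r = -0.893 (adjusted p = 0.0129; -0.999) and rho = -1.0 (adjusted p = 0.000596). The effective length split was argued against as the whole cause. On one side of it WT HSD 1 and 2 had at least 172.99 times the Dbp level of WT NSD 1 and 2. Replicates 3, on the other side, are not in that ratio. Diet and collection time cannot be told apart. Dbp had a log2 fold change of -2.22 in the additional set (SE 2.07, adjusted p = 0.628 by edgeR), and collection times are not given. The inverse relation within each diet (rho at most -0.786) may reflect animals taken at different hours.

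Neutrophil markers were higher in the labelled knockout on both diets. More blood left in the livers was argued against on high salt, since erythroid markers had a median log2 fold change of -0.311 there (-0.7 to -0.103 without single libraries of the groups compared), where neutrophil markers stood at 3.34 (2.02 to 3.7). On normal salt the medians were 0.688 and 4.32. A smaller share of hepatocyte RNA would raise the markers of the other cell types alike, and was argued against on high salt. Stellate cell and matrix genes stood at -0.456 there, sinusoidal endothelial markers at -0.421 and B cell markers at -0.09 (-1.3 without KO HSD 3, adjusted p = 0.00556, adjusted p = 0.343 with an estimated correlation), while MHC class II genes stood at 0.264 (0.483 without KO HSD 1), Kupffer cell markers at 0.34 and T and NK cell markers at 1.12. Without KO HSD 1, on which the first 2 values largely rest, they were -0.184 and -0.086, with neutrophil markers at 2.02. On normal salt the medians lay apart but all above 0, at 0.092 for stellate, 0.459 for endothelial, 0.913 for B cell, 1.18 for MHC class II, 1.78 for Kupffer cell and 4.32 for neutrophil markers. A smaller share as a part of the rise on normal salt therefore stays open. The labelled genotype stays open: 5 of the 6 libraries labelled knockout lay above the highest wild-type library (WT NSD 1, mean level -0.208), and KO HSD 3 at -0.356 lay below it. It cannot be told apart from strain background or cohort, which the design does not separate from the labels, and Sirt3 had a log2 fold change of -0.03 on normal salt.

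Other splits of the same libraries were fitted in the same way. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. On normal salt 1 split, the real one with 54 genes between the labelled genotypes, gave as many, and the highest other gave 0. On high salt both the real split and the highest other gave 0 (10 of 10 splits as large; 603 with an unadjusted p under 0.05 by edgeR in the real split, DESeq2 29, limma-voom 0). For salt in the wild type the real split gave 0 and the highest other 1 (10 of 10 as large; 584 unadjusted, DESeq2 9, limma-voom 56), while among the 4 splits that part all 3 replicate pairs the highest other gave 0. For salt in the labelled knockout the real split gave 0 and the highest other 18 (10 of 10 as large; 1051 unadjusted, DESeq2 50, limma-voom 139). That split set KO HSD 1, KO NSD 1 and KO NSD 3, with the highest female-biased levels, against the rest, which points to a structure of the samples. For the interaction the real split gave 0 genes and the highest other of the 100 splits drawn 12 (706 unadjusted, DESeq2 10, limma-voom 0). A real split with 0 genes is matched by every split, so its count (100 of 100) decides nothing, there as in the comparisons above with 0 genes. By genes with an unadjusted p under 0.05, 40 of the 100 splits gave at least the 706 of the real one.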

How the results depend on the processing

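Fits without KO NSD 1 and KO NSD 3, without WT HSD 3 and WT NSD 3, without 3 labelled knockout libraries, with the effective length offset, with 9 pooled wild-type libraries or with a block in the wild type alone, camera without single libraries, and the alternatives for the genotype agreement, were chosen after seeing the data. DESeq2 size factors, no filter and the stricter filter kept every gene count within 1.5 times, except that the stricter filter left 1 gene in the additional set; no scaling moved the median of all genes by over 0.1. DESeq2 gave 9 genes (salt in wild type), 50 (salt in the labelled knockout), 661 (genotype on normal salt), 29 (genotype on high salt), 10 (interaction) and 30 (additional set). Limma-voom gave 56, 139, 1604, 0 and 0 for the first 5. The replicate block gave 1 gene for salt in the labelled knockout and 98 for genotype on normal salt. There upper-quartile scaling gave 35, only the 2 groups 175, all 15 libraries 106 and the offset covariate 385. That covariate gave 0 by edgeR in salt in wild type (851 with an unadjusted p under 0.05) and in the interaction (1264). Leaving out the 2 libraries without Y-linked transcripts, or the 3 labelled knockout libraries with the highest female-biased levels, gave 0 (969 and 968 with an unadjusted p under 0.05 by edgeR). Leaving out WT HSD 3 and WT NSD 3, which share a replicate number and are offset in effective length, gave 30 genes for salt in wild type, 6 for the interaction and 74 for genotype on normal salt (18 higher, 56 lower). Salt in the 9 wild-type libraries pooled with a term for the split gave 1. The wild-type block gave 1. Replicate numbers correlated above 0.1 in 5 of 12 pairs (-0.236 to 0.484). Leaving out single libraries gave 0 to 10 genes (salt in wild type, 10 without WT HSD 3), 0 to 21 (salt in the labelled knockout, 21 without KO NSD 2), 5 to 420 (genotype on normal salt, 5 without WT NSD 2 and 420 without KO NSD 2), 0 to 7 (genotype on high salt, 7 without KO HSD 3), 0 to 8 (interaction, 8 without KO NSD 2) and 1 to 1 (additional set, another gene each time). The agreement of the wild-type sets ranged from -0.28 (without WT HSD 3) to 0.082 (WT NSD 3), changing sign also without WT HSD 1 (0.027) and WT HSD 2 (0.028), and was -0.217 above 5 CPM. That of wild type and labelled knockout ranged from -0.095 to 0.022 (KO NSD 1), with 0.001 without KO HSD 1 and 0.035 without the 2 libraries. That of the genotype effects ranged from 0.315 (KO HSD 1; 0.344 KO HSD 2, 0.316 WT HSD 3) to 0.451, with 0.261 without the 2 libraries and 0.561 above 5 CPM. Lists called by camera fell to 0 in all 5 contrasts with an estimated correlation and in directional fry, and by mixed fry to 0 in salt in wild type, genotype on high salt and the interaction and to 5 in salt in the labelled knockout. Without single libraries camera called 7 to 11, 14 to 19, 11 to 16, 14 to 22 and 16 to 21 lists in the 5 contrasts. It changed the sign of proliferation on high salt (adjusted p = 0.96 without WT HSD 1; 6.59e-09 at the other end, without WT HSD 3) and of interferon response in the interaction (0.904 without WT NSD 1; 8.24e-10, without WT NSD 2). The wild-type block gave 11 and leaving out the 2 libraries 10 in the interaction. Without these 2 libraries signs changed for H2-DMb1 (0.121), H2-DMa (0.454), Ciita (0.348), Cd74 (0.75), Cyp3a41a (6.02) and Cyp3a41b (1.70) in salt in the labelled knockout. They changed for H2-Aa (-0.201), Cd22 (-0.14), Cdh5 (-0.141) and Cyp3a41a (-4.56) in genotype on normal salt, and for Sirt3 (0.078), Cd74 (0.289), H2-Aa (0.474), H2-DMa (0.309), Cd22 (0.158), Tgfbi (0.127) and Cyp3a41a (4.79) in the interaction. The same omission changed the sign of lists, with adjusted p = 0.406 (inflammatory), 0.00381 (MHC class II), 0.559 (T and NK cell) and 0.518 (stellate) in salt in the labelled knockout. It was 0.929 (MHC class II) in genotype on normal salt, and 0.495 (inflammatory), 0.38 (MHC class II), 0.711 (stellate) and 0.379 (cholesterol synthesis) in the interaction. Single libraries changed the sign of Sirt3 (0.07 without KO NSD 2 and 0.05 without KO NSD 3 on normal salt, 0.085 without KO NSD 1 in the interaction, against -0.275 and -0.266 at the other end) and of Ccnb2 (0.041 without WT HSD 1 on high salt, -2.12 without WT HSD 3). Of the values of single genes and lists 7897 kept their direction and side of the threshold, 185 passed it, 225 no longer did and 32 changed sign.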

Other observations

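The tests of genes shared between the diets by 10 Mb windows were chosen after the results were seen; that of genes near Sirt3 was written down beforehand. The list tests without single libraries and without KO NSD 1 and KO NSD 3 were added after seeing the data.

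Several functions of the liver cell showed no call as lists in any pairwise comparison at the preset correlation of camera with all 12 libraries. Oxidative phosphorylation genes lay at median log2 fold changes of 0.091 (salt in wild type, adjusted p = 0.157), 0.033 (salt in the labelled knockout, 0.406), -0.001 (genotype on normal salt, 0.755) and -0.067 (genotype on high salt, 0.258). In the same order, ribosomal proteins lay at 0.067, 0.055, 0.071 and 0.052 (adjusted p = 0.246, 0.274, 0.504 and 0.233), urea cycle genes at 0.129, -0.047, 0.113 and 0.064 (0.698, 0.718, 0.248 and 0.319). Xenobiotic P450 enzymes lay at 0.158, 0.237, 0.097 and 0.216 (0.583, 0.137, 0.938 and 0.245), with a mean of opposite sign in the first of these (-0.01). Sirtuins (0.092, -0.015, -0.027 and -0.084) and neighbours of Sirt3 (-0.006, -0.096, 0.175 and 0.085) did not pass either (adjusted p = 0.629, 0.674, 0.938 and 0.747, and 0.852, 0.112, 0.131 and 0.504). The unfolded protein response (0.169, -0.411, 0.683 and -0.003; adjusted p = 0.181, 0.46, 0.131 and 0.948) and heat shock genes (-0.164, -0.373, 0.349 and 0.293; 0.852, 0.572, 0.285 and 0.245) were called without KO NSD 1 and KO NSD 3 in the labelled knockout on salt (adjusted p = 7.66e-12 and 0.00381, lower) and between genotypes on normal salt (1.29e-13 and 0.00122, higher). The unfolded protein response then had adjusted p = 0.0599 and 0.0448 with an estimated correlation. In these fits KO NSD 2 stands alone and is assumed to vary like the other groups. Its mean level of the unfolded protein response was 0.859, against -0.406 and -0.007 in the libraries left out, so the calls are the level of 1 library. Osmotic response genes (-0.014, -0.062, -0.076 and -0.046; adjusted p = 0.535, 0.624, 0.909 and 0.674) and markers of adipose tissue, pancreas and muscle (-0.031, 0.985, -0.37 and -0.595; 0.819, 0.112, 0.142 and 0.615) did not pass, though Cfd fell on normal salt. Glucocorticoid targets were called on high salt between genotypes and lay at 0.012, -0.007 and 0.09 elsewhere (0.834, 0.335 and 0.504). The test pointed opposite to the median, without passing, for glucocorticoid targets, inflammatory cytokines and NOD-like receptor genes (salt in wild type), glucocorticoid targets, sirtuins and lipogenesis genes (salt in the labelled knockout; the last -0.039, 0.484), osmotic response genes (genotype on both diets) and ribosomal proteins (interaction; -0.027, 0.972). So it did for cholangiocyte markers (0.157, 0.876) and cholesterol synthesis (0.125, 0.938) between genotypes on normal salt and for clock genes (-0.084, 0.647) and the unfolded protein response on high salt.

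Leaving out 1 library of the groups compared brought calls for some of these lists, with adjusted p = 0.147 to 0.992 with an estimated correlation. In salt in the wild type these were oxidative phosphorylation (adjusted p = 0.0178 without WT NSD 1, 0.000141 without WT HSD 3) and ribosomal proteins (0.00434 and 0.00282 without the same libraries). In salt in the labelled knockout they were ribosomal proteins without KO HSD 1 (0.046), xenobiotic P450 enzymes and glucocorticoid targets without KO HSD 3 (0.00517 each), and the unfolded protein response and heat shock genes without KO NSD 1 (0.00158 and 0.0016). Between genotypes on normal salt they were the unfolded protein response without KO NSD 3 or KO NSD 1 (0.0349 and 5.63e-05), heat shock genes without KO NSD 1 (0.000475) and markers of adipose tissue, pancreas and muscle without WT NSD 3 (0.00727). On high salt they were oxidative phosphorylation without WT HSD 3 (1.89e-05), ribosomal proteins without KO HSD 1 or WT HSD 2 (0.0282 and 0.0026), and urea cycle genes and xenobiotic P450 enzymes without KO HSD 3 (0.00584 and 0.0039).

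Some genes differed between the labelled genotypes on both diets. With an unadjusted p under 0.05 and one direction on both diets there were 179 of 13001 placed genes (135 higher, 44 lower in the labelled knockout), against 43.1 expected if the 2 contrasts and the genes were independent. They are not: deviations of wild-type libraries with the same number correlated across the diets (r = 0.108 to 0.484), which can give both contrasts one direction, and no value here allows for that. Of the 108 genes tested within 10 Mb of Sirt3, 1 was among the 179 (0.673 times expected), so most lie elsewhere. This count cannot tell whether a segment from another strain came with Sirt3. Clusters elsewhere stay open: 2 windows held at least 5 such genes, on chromosome 4 (Zfp979, Pik3cd, Zfp982, Zfp992, Zfp991) and on chromosome 19 (Gm4952, Ms4a4b, Ms4a8a, Keg1, Ms4a6d), and 15.15% of 10000 random gene sets held as many. Strain variation there may or may not take part. Zfp991 stood at 1.69 CPM in the normal salt library of the additional set, near the labelled knockouts (0.88 to 2.14 CPM) and below the other wild-type libraries (4.71 to 11.8 CPM).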
